A study of Mus musculus with 4 samples.

How the data were processed

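Total RNA from chemically transformed C3H10T1/2 cells, a mouse embryo fibroblast line, was measured on 4 one-colour Agilent arrays, 2 from untreated transformed cells (control) and 2 from transformed cells exposed to phorone. Per the labels' protocols, cells had received 2.5 µg/ml of 3-methylcholanthrene for 2 days and, 4 days later, 100 ng/ml of the phorbol ester TPA for 2 weeks, followed by 4 weeks in normal medium. The phorone arrays carry a dose of 2 mM in the labels. The length of the exposure and the vehicle are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The labels do not say that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

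Per the file headers, the deposited intensity values came from Agilent Feature Extraction 10.7.3.1 on a custom mouse design, with Cy3 as the single dye. The processed signal in these deposited files is an intensity with the local background subtracted, detrended across the array, and with surrogate values in place of very dim spots; it is not normalised between arrays. The authors' deposited value table holds log2 values of the same probes. Set against the scanner values, each of its columns was the log2 processed signal minus a single number per array, with an SD of at most 0.0195 around that number, and its column medians were -4.39, -4.35, -4.37 and -4.30. Its scale is thereby known, and its centring lies at the 75th percentile of each array. All 4 arrays lay on 1 slide in 1 scan. The control arrays lay in 1 row of the slide and the phorone arrays in another, so row and group cannot be told apart. The 2 columns each held a control and a phorone array of the same replicate number, so the replicate block is also a block of the column.

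Each array held 61657 spots outside the controls, for 61307 probes, of which 40628 were gene probes and 20679 were probes for noncoding transcripts. The scanner software called 52.3% and 52.7% of the spots well above background on the control arrays, and 52.2% and 51.1% on the phorone arrays. The 75th percentile of the signal was 701 and 747 on the control arrays and 563 and 572 on the phorone arrays, and no spot was saturated. The number of arrays limits the precision of every value. Gene probes were named through their RefSeq accession with a table of the GRCm38.p6 assembly, which matched 28136 of them (69.3%); the others kept the name of the array design. No coordinates were used, because the probe positions in the files refer to another build.

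From the processed signal, log2 values were taken, each array's 75th percentile over all probes outside the controls was subtracted, and spots of the same probe were averaged. Spots flagged as outliers were left out, which removed 111 probes. A probe was kept if it was well above background on both arrays of at least 1 group, and the brightest kept probe stood for its gene, which gave 17033 genes. Of 5612 genes with more than 1 kept probe, 208 had probes called in opposite directions. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model with empirical Bayes moderation, two-sided, 2 residual degrees of freedom and 3.03 prior degrees of freedom), and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Fold changes are differences of mean log2 values, phorone minus control, given with their standard error (SE). A gene not well above background on either array of a group has only a bound there: the mean of the brighter group was set against, per array, the higher of the gene's own value and the lowest value among probes well above background.

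Before the data were examined, 31 gene lists were fixed, and 28 of them had at least 4 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. With an estimated correlation camera works on the 2 residual degrees of freedom, so it could hardly call any list here. The lists covered NRF2 targets, glutathione metabolism, heat shock, endoplasmic reticulum and ATF4 responses, metallothioneins, p53, apoptosis, mitosis, replication, repair, ribosome biogenesis, immediate early, NF-kB, interferon and TGF-beta genes, matrix, proteases, actin, cholesterol, glycolysis, autophagy, proteasome, aryl hydrocarbon receptor targets and markers of 7 other cell types. Some lists shared genes. NRF2 targets shared 3 with glutathione metabolism and 1 each with the ATF4 (Slc7a11), autophagy (Sqstm1) and aryl hydrocarbon receptor (Nqo1) lists. A further 6 lists were written after the data had been seen. The named genes followed a rule fixed beforehand: the 10 largest called changes each way among genes above background on all 4 arrays, up to 2 called members each way per list, up to 5 genes each way detected in a single group, and a set of stress, cell cycle and matrix genes given whatever their values. Names of clones and accession-like names were left out, and some genes that the rule names are not reported here. Probes for noncoding transcripts were fitted separately.

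Data were simulated from the means of these 17033 genes, with spreads drawn from the prior fitted to them and 200 genes changed. Limma called 0 of 50 genes changed by 0.5 on the log2 scale and 2 of 50 changed by 1. It called 40 of 50 changed by 2 and 48 of 50 changed by 4. With so few genes changed, the adjusted threshold was stricter than in the data, where 45.5% of genes were called. These shares therefore do not give the power of the main fit. Of 96 simulated calls, 6 were false. A simulated list of 25 genes moved by 1 was called, and 0 of the unmoved lists were. Alternatives were quantile or median scaling, normexp background correction with an offset of 50, the authors' values, other filters on dim probes, the mean of a gene's probes, another variance model, the replicate number as a block and each array left out in turn. Scaling by 7 spike-in probes, removal of a corner with dark probes on an array and a joint fit with the noncoding probes were added after the data had been seen.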

Results

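Gene expression was measured in transformed C3H10T1/2 mouse fibroblasts without (control, n = 2 arrays) and with 2 mM phorone (n = 2 arrays). Phorone is an unsaturated ketone that is conjugated to glutathione and depletes it. Across genes, log2 values of the 2 control arrays correlated with r = 0.988 and those of the 2 phorone arrays with r = 0.996, against 0.939 to 0.951 between groups (across genes, which are not independent replicates). Between 51.1% and 52.7% of spots were well above background on each array, and signals are given as log2 values relative to each array's 75th percentile.

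The comparison asked which genes differed between phorone-exposed and unexposed transformed cells. The glutathione transferases Gsta3 and Gsta1 rose most among the genes detected on all 4 arrays apart from unnamed clones, Gsta3 from -2.72 ± 0.05 to 3.19 ± 0.10 (SD, n = 2 each), a log2 fold change of 5.90 (SE 0.13, limma adjusted p = 0.000186). Gsta1 rose by 9.17, and its close paralog Gsta2, not well above background in control cells, rose at least 352-fold. Probes of such near-identical genes may share signal, so both values are uncertain. Slc7a11, the cystine carrier that supplies cysteine for glutathione, rose by 5.78 (SE 0.22), Srxn1 (sulfiredoxin) by 4.13 (SE 0.13) and Afp, the fetal serum protein alpha-fetoprotein, by 5.50 (SE 0.19). The amine oxidase Aoc3 fell by 6.65 (SE 0.13). Tgfbi, a matrix protein induced by TGF-beta, fell by 6.56 (SE 0.16), and the proteoglycans Prelp and Aspn fell by 5.72 and 5.40. In all, 4132 genes were higher and 3624 lower with phorone among 17033 tested (45.5% called by limma), of which 1367 and 2051 changed at least 2-fold.

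Targets of NRF2, the transcription factor of the oxidant response, rose together: 19 of 25 measured members were higher and 0 lower (20 and 0 adjusted over the list alone), with a median log2 fold change of 1.60. Camera called NRF2 targets higher (adjusted p = 0.324 with an estimated correlation). Hmox1 (haem oxygenase) rose by 2.61 (SE 0.24), Nqo1 (quinone reductase) by 2.61 (SE 0.12), Txnrd1 (thioredoxin reductase) by 1.98, and Gclm and Gclc, the subunits of the enzyme that starts glutathione synthesis, by 3.24 and 2.59. Glutathione metabolism was divided, with 13 of 32 members higher and 11 lower (13 and 11 adjusted over the list alone) and no shift of the list by camera, except under spike-in scaling (higher, adjusted p = 0.00419). Lower members numbered 4 under spike-in scaling and 6 with no filter on dim probes. Anpep, an aminopeptidase acting in glutathione breakdown, and the transferase Gstt1 fell by 3.58 and 3.39. Among targets of the aryl hydrocarbon receptor, 3 of 7 were higher and 1 lower (3 and 1 adjusted over the list alone), with 3 and 2 without control replicate 2, and 2 and 0 without phorone replicate 2 or under spike-in scaling. Camera did not call this list, except under spike-in scaling (higher, adjusted p = 0.0142). Cyp1a1, the best known target, was not well above background in control cells and rose at least 7.37-fold, whereas Cyp1b1 fell by 0.81. Nqo1, given above among NRF2 targets, was another of the higher members.

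Of 32 proteasome genes, 30 rose and 0 fell (30 and 0 adjusted over the list alone; median 0.97), among them Psmc6 by 1.42 and Psma5 by 1.37. Camera called proteasome genes higher (adjusted p = 0.385 with an estimated correlation). Of 21 heat shock chaperones, 15 rose and 1 fell (15 and 1 adjusted over the list alone; median 1.01), with Hspa4l higher by 3.22, Hsph1 by 2.05 and the small chaperone Cryab lower (-0.60), though 0 were lower under spike-in scaling or with any array but control replicate 1 left out. Camera called heat shock chaperones higher (adjusted p = 0.463 with an estimated correlation). Hspa1b, also fixed in advance, was not analysed here. The list of endoplasmic reticulum chaperones and associated degradation went both ways, 4 of 19 members higher and 9 lower (5 and 10 adjusted over the list alone). Among its members Dnajb9 was higher by 1.07 and Hyou1 by 0.69, and Xbp1 and Calr (calreticulin) were lower (-1.48 and -1.23). These counts fell to 1 higher and 3 lower without phorone replicate 1 or with no filter, to 1 and 4 without phorone replicate 2 and to 2 and 0 under spike-in scaling. The list median of -0.42 stood at 0.09 under spike-in scaling and at 0.051 with the mean of a gene's probes. Targets of ATF4, the factor of the integrated stress response, were not shifted as a list, with 7 of 33 higher and 5 lower (6 and 5 adjusted over the list alone). With either phorone array left out or no filter 2 were higher and 4 lower, against 5 and 9 without control replicate 1, 4 and 6 under quantile normalisation and 3 and 1 under spike-in scaling. In this list the amino acid carrier Slc7a3 rose by 0.97, Aldh18a1 of proline synthesis fell by 1.59, and the hormone gene Fgf21 was at least 2.20-fold lower. The stress markers Ddit3, Atf3 and Trib3 were not called, with log2 fold changes of -0.53, -0.30 and -0.33 (adjusted p = 0.193, 0.203 and 0.434 in limma). Without control replicate 1, Ddit3 (-0.93) and Trib3 (-0.80) were called lower. In the autophagy and lysosome list 10 of 24 members rose and 3 fell (10 and 3 adjusted over the list alone), including the autophagy receptor Sqstm1 by 1.62 and the lysosomal enzyme Gla by 2.00, while Lamp2 (with 0.37 on another probe, not called) and Hexa fell by 0.68 and 0.67. Without phorone replicate 1, 7 members were higher and 1 lower, against 7 and 0 without phorone replicate 2, 6 and 0 with no filter, 8 and 0 under spike-in scaling and 12 and 1 with the mean of a gene's probes. Camera did not call this list (adjusted p = 0.0510), but did without phorone replicate 2 (0.0387), with the mean of a gene's probes (0.0280) and with noncoding probes in the fit (0.0392). Of 8 metallothionein and zinc transport genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone): Slc30a1, a zinc exporter, by 1.16 (with -0.35 on another probe, not called) and Slc30a5 by 0.56. With either phorone array left out, or under spike-in scaling, 1 was higher, and without control replicate 1, 2 were higher and 1 lower. Mt1 and Mt2 had log2 fold changes of -0.17 (SE 0.55) and 0.13 (SE 0.39) and were not called. Mt1 was called lower without control replicate 1 (-1.02) and higher without control replicate 2 (0.67).

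Of 23 ribosome biogenesis genes, 21 rose and 0 fell (21 and 0 adjusted over the list alone; median 0.77), with Rrp12 and Rrp9, processing factors of ribosomal RNA, higher by 1.90 and 1.41. Higher members numbered 13 without phorone replicate 1, 10 without phorone replicate 2 and 11 with no filter. Camera called ribosome biogenesis genes higher (adjusted p = 0.463 with an estimated correlation). Of 35 replication genes, 23 rose and 3 fell (26 and 4 adjusted over the list alone; median 0.59), including the licensing factor Cdt1 by 1.55, Mcm3 by 1.25 and Mcm5 by 0.86, while the nucleotide enzymes Tk1 and Rrm2 fell by 1.86 and 0.84. Without phorone replicate 1, 15 were higher and 1 lower, against 10 and 2 without phorone replicate 2, 17 and 1 without control replicate 2, 16 and 1 under spike-in scaling and 12 and 1 with no filter. Camera called replication genes higher (adjusted p = 0.463 with an estimated correlation). Mitosis genes were not shifted as a list, with 10 of 30 higher and 3 lower (8 and 1 adjusted over the list alone): Ccnb1 (cyclin B1) rose by 1.11 (with -0.24, not called, to 1.13, called, on its other probes) and the kinase Aurka by 0.94, while Nusap1 and Ccna2 fell by 0.63 and 0.62. Without phorone replicate 1 camera called the list higher (median 0.35, adjusted p = 0.0404). In that fit 7 members were higher and 0 lower, and these counts were equal under spike-in scaling. Without control replicate 1, control replicate 2 and phorone replicate 2, 10, 6 and 4 were higher and 1, 1 and 2 lower, and with no filter 5 were higher and 0 lower. Of 30 repair genes, 11 rose and 5 fell (11 and 5 adjusted over the list alone), with the glycosylase Ogg1 higher by 1.35, Brca1 by 1.03, and the glycosylases Mutyh and Nthl1 lower (-2.06 and -0.56). Without phorone replicate 1, or with no filter, 5 were higher and 1 lower, against 4 and 1 without phorone replicate 2 and 6 and 1 under spike-in scaling. Lower members numbered 3 without control replicate 1 and 1 without control replicate 2. Of 27 p53 targets, 9 rose and 6 fell (12 and 6 adjusted over the list alone), with 5 and 5 without phorone replicate 2, 5 and 3 with no filter and 7 and 0 under spike-in scaling. Among these the death receptor Tnfrsf10b rose by 1.54 and Mdm2, the ligase that degrades p53, by 0.91, Ddit4l was at least 1.34-fold higher, Btg2 and Dcxr fell by 1.39 and 1.34, and Cdkn1a was not called (-0.24, adjusted p = 0.371 in limma). Of 22 apoptosis regulators, 0 rose and 6 fell (0 and 6 adjusted over the list alone), including the cell death inducers Bcl2l11 (-1.59) and Bmf (-1.53). Another probe of Bcl2l11 was higher, by 1.31. Other probes of Apaf1 (0.91 and 1.91) and Xiap (2.10) were called higher, though neither gene was on its brightest probe. Other probes of Bmf (-2.41) and Cflar (-0.93) were called lower. Lower apoptosis members numbered 3 without phorone replicate 1 or with no filter, 2 without phorone replicate 2 and 0 under spike-in scaling, while 1 was higher without control replicate 1 and 2 without control replicate 2 or with the mean of a gene's probes. With all 4 arrays, camera called none of the mitosis, repair, p53 and apoptosis lists. Fry called repair and p53 genes higher (adjusted p = 0.0370 and 0.0267) and apoptosis genes lower (0.0281), but not mitosis genes (0.149).

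**Figure D1:**
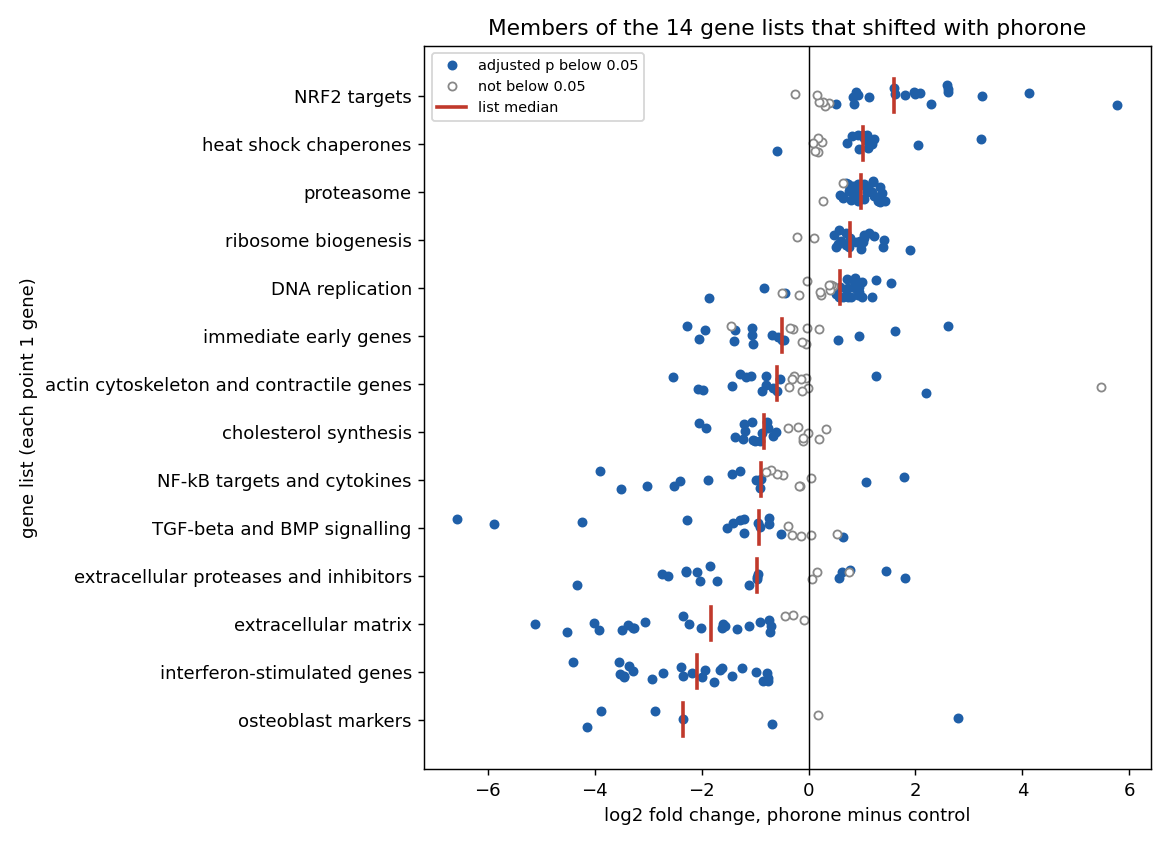
Log2 fold changes (phorone minus control, x axis) of the measured members of the 14 gene lists that camera called, 1 list per line, with filled points for genes called by limma, open points for the others and a bar at the list median. All 24 interferon-stimulated genes lie below 0 and 30 of 32 proteasome genes are called higher. Genes not above background in a group are drawn at their measured value. Ankrd1 of the actin list is drawn at 5.48, through a probe that was dark on control replicate 2.

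All 24 interferon-stimulated genes fell (24 adjusted over the list alone), with a median of -2.09, or -1.96 with genes at their bound. Camera called interferon-stimulated genes lower (adjusted p = 0.463 with an estimated correlation). Iigp1, a GTPase induced by interferon, fell by 4.40 (SE 0.51), Mx1, an antiviral GTPase, was at least 2.42-fold lower, and Zbp1 and Ifi27l2a fell by 5.32 and 5.07. Of 20 NF-kB targets and cytokines, 2 rose and 11 fell (2 and 14 adjusted over the list alone; median -0.90). The chemokine Cxcl5 fell by 3.51 and the cytokine Il6 by 0.89, Ccl20 was at least 6.49-fold lower, and Ptgs2, a cyclooxygenase, and Il1rl1 rose by 1.78 and 1.07, with -0.24 on another Il1rl1 probe, not called. Camera called NF-kB targets lower (adjusted p = 0.324 with an estimated correlation). Of 23 immediate early genes, 4 rose and 12 fell (4 and 12 adjusted over the list alone). The median was -0.49, but 0.02 under spike-in scaling, where 3 were higher and 3 lower. With either phorone array left out 2 were higher, and with no filter 2 were higher and 7 lower. Camera called immediate early genes lower (adjusted p = 0.455 with an estimated correlation), though not under spike-in scaling (adjusted p = 0.147). Egr1 and Fos fell by 2.28 and 2.05, and Fosl1 and Maff rose by 2.60 and 1.61. Under spike-in scaling 15 interferon-stimulated genes and 6 NF-kB targets were called lower, with medians of -1.57 and -0.38.

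Of 24 extracellular matrix genes, 0 rose and 21 fell (0 and 21 adjusted over the list alone), with a median of -1.81, or -1.61 with genes at their bound. Camera called matrix genes lower (adjusted p = 0.324 with an estimated correlation). The collagen chain Col6a3 fell by 5.11 (SE 0.12) and the proteoglycan Dcn (decorin) by 4.52 (SE 0.12). Col1a1 was not called on its brightest probe (-0.30, adjusted p = 0.0939 in limma) but was called lower on its other probes (-2.21 and -1.44). Col1a1 was called lower under 5 alternatives, quantile normalisation among them, and stood at 0.21 under spike-in scaling, which left 12 matrix genes called lower. Of 20 TGF-beta and BMP genes, 1 rose and 14 fell (1 and 14 adjusted over the list alone; median -0.92). Under spike-in scaling 0 were higher and 4 lower (median -0.41), and with no filter 0 and 9. Without control replicate 2 or phorone replicate 2, 0 were higher. Grem1, an antagonist of BMPs, was at least 11.9-fold lower, and the inhibitor Smad7 rose by 0.65. Camera called TGF-beta genes lower (adjusted p = 0.324 with an estimated correlation). Of 21 extracellular proteases and inhibitors, 5 rose and 13 fell (6 and 13 adjusted over the list alone; median -0.97). Mmp3 (stromelysin) was at least 4.99-fold lower and Plau (urokinase) at least 1.43-fold lower, while Plaur, the urokinase receptor, and the protease Adam8 rose by 1.80 and 1.45. Higher members numbered 3 without phorone replicate 2 or with no filter. Camera called protease genes lower (adjusted p = 0.463 with an estimated correlation). Of 23 actin and contractile genes, 2 rose and 13 fell (2 and 13 adjusted over the list alone; median -0.59). Myl9 and the smooth muscle actin Acta2 fell by 2.53 and 2.06, whereas Cnn1 and Actb rose by 2.21 and 1.27. Cnn1 was well above background on only 1 control array, so its fold change is uncertain. Ankrd1 stood at 5.48, not called, through a probe that was dark on control replicate 2 (-6.80, against 3.28 on control replicate 1). Camera called actin genes lower (adjusted p = 0.463 with an estimated correlation), though not under spike-in scaling (adjusted p = 0.311), where 3 were higher and 3 lower with a median of -0.08.

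**Figure D2:**
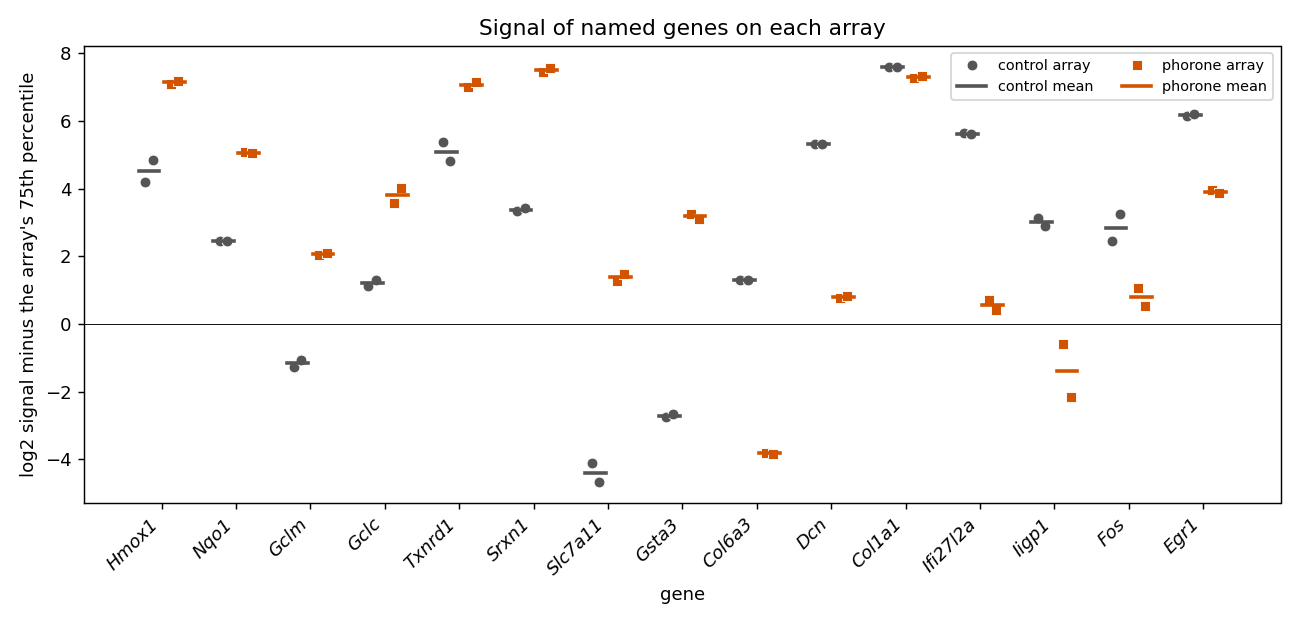
Log2 signal minus the array's 75th percentile (y axis) of 15 named genes on each of the 2 control arrays (circles) and 2 phorone arrays (squares), with the mean of each group as a line. Slc7a11 rose from -4.39 to 1.38 and Dcn fell from 5.33 to 0.80, while the group means of Col1a1 on its brightest probe were 7.60 and 7.30.

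Of 22 genes of the cholesterol synthesis list, 0 rose and 15 fell (0 and 15 adjusted over the list alone; median -0.82). Under spike-in scaling 2 were called lower (median -0.31). Camera called cholesterol genes lower (adjusted p = 0.463 with an estimated correlation). Of 24 glycolysis and hypoxia genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone); the median was 0.04 while camera's direction was lower, without a call. Lower members numbered 2 without phorone replicate 2 or with no filter, and 0 under spike-in scaling. The glucose carrier Slc2a1 rose by 1.24 and Vegfa by 1.46, with -0.98 on another Vegfa probe, and Pfkfb3 and Pdk1 fell by 1.52 and 1.39.

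Of 7 osteoblast markers, 1 rose and 5 fell (1 and 5 adjusted over the list alone), with a median of -2.34, or -0.80 with genes at their bound; Omd fell by 3.89, Alpl (alkaline phosphatase) was at least 5.90-fold lower and Phex at least 2.31-fold higher. Camera called this list lower (adjusted p = 0.463 with an estimated correlation), but not under quantile normalisation, median scaling, normexp with the 75th percentile or without control replicate 1 (adjusted p 0.0502 to 0.0815). All 3 measured chondrocyte markers fell, including Comp by 3.20 (well above background on only 1 phorone array) and Col2a1 by 3.08. Of 3 muscle markers 2 fell, Acta1 by 2.07 and Des by 1.79. The chondrocyte and muscle lists were too small to test. Of 4 adipocyte markers 2 fell, Lpl by 0.83 and Fabp4 by 0.65, but 0 were called under spike-in scaling and 1 with any array but control replicate 2 left out. Of 4 epithelial markers Krt7 fell by 1.61, and of 2 endothelial markers Esam was at least 1.82-fold higher and Tek at least 1.68-fold lower. Of 4 macrophage and blood cell markers, Cd68 rose by 1.26 and Lyz2 fell by 1.74; the list median was 0.69, camera's direction was higher and fry's was lower, without a call. Here 2 were higher without control replicate 2 or under spike-in scaling. Of the epithelial markers 1 was higher without phorone replicate 2, and 1 higher and 0 lower under spike-in scaling. Counts of these 7 lists were the same adjusted over the list alone, and camera called none of the adipocyte, epithelial and macrophage lists.

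Among called genes, 219 were well above background with phorone but on neither control array, and 472 the reverse. By their bounds, Vgf, Glyat (glycine acyltransferase), Spdye4b and Rnf183 were at least 19.1-fold, 16.3-fold, 15.7-fold and 13.3-fold higher, and Itga8 (integrin alpha 8), Cyp2f2, the aminopeptidase Enpep, Slc15a2 and Inmt at least 48.4-fold, 43.3-fold, 42.4-fold, 34.6-fold and 31.2-fold lower. The other genes with the largest rises on all arrays were Slc16a6 (4.07), Uchl1 (3.89), Syt13 (3.83, with 0.40 on another probe), Dppa5a (3.64) and Shtn1 (3.53), and those with the largest falls were Serpina3g (-5.45), Olfml3 (-5.36) and Rarres2 (-5.15).

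Higher calls were 53.3% of all calls, but 73.7% (2931 higher, 1046 lower) under spike-in scaling, which moved the median of all genes from 0.08 to 0.60 on the log2 scale. That move rests largely on control replicate 2, whose spike-in level (13.1) was above those of the other arrays (12.3, 11.9 and 11.7). The count of higher genes fell to 2305 with no filter on dim probes, to 2516 without phorone replicate 1 and to 2086 without phorone replicate 2, and normexp correction gave 852 genes higher and 1359 lower by at least 2-fold. With an array left out in turn, 16 named genes lost their call in at least 1 of the fits (highest adjusted p = 0.214, limma), each with its direction kept: Bmf, Ccna2, Cryab, Cyp1b1, Fabp4, Hexa, Hyou1, Il6, Lamp2, Mcm5, Nthl1, Nusap1, Pdk1, Rrm2, Slc30a5 and Smad7.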

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

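The tests of the corner position, of the list medians across scalings, of macrophage markers, of body position genes and of growth arrest genes were chosen after the results had been seen.

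Probes for noncoding transcripts, whose fold changes were left out of the gene counts and lists above except in a joint fit tried as an alternative, also differed between the groups: of 7698 tested separately with limma, 485 were higher and 425 lower with phorone, 342 and 337 of them at least 2-fold. Fitted jointly with the genes, an alternative added after the data had been seen, 992 were higher and 800 lower. They are given here as a signal outside the main comparison of genes.

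On control replicate 2, 72 probes that were bright on control replicate 1 were lower by more than 3 on the log2 scale, against 27 to 73 such probes on the other arrays relative to their own replicate. On control replicate 2 79.2% of them lay in a single corner, which holds 1.19% of the bright probes, while on the other arrays no window of that size held more than 23.3%. Other probes of the same genes differed between the control arrays by a median of -0.00025 (32 probes, from -0.52 to 0.34), and this argues against lower expression of these genes in that sample. Of the 260 bright probes in that corner 21.9% were dark, and a candidate explanation is failed hybridisation in a part of it. The main fit kept the corner, and 30 of the tested genes stood on such a dark probe, among them Ankrd1 of the actin list. Without the corner, 4172 genes were higher and 3659 lower.

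All 24 interferon-stimulated genes were lower with phorone. Array scaling was tested first by the number of members still called, with at least 20 set beforehand as speaking against it. The fewest was 15, under spike-in scaling. That scaling also widened the spread between the control arrays, so lost calls need not mean a smaller shift, and the question stayed open. A second test, added once that outcome was known, took the list median over the 3 scalings. It was -1.57 at its highest, with an upper quartile of at most -0.87. Spike-in scaling moves every gene by the same amount (the median of all genes from 0.08 to 0.60), so the -1.57 followed from that amount. These 3 scalings therefore do not account for the whole of the shift, but may for a part of it. Macrophages or blood cells in the control samples were tested with their markers: 6 of 10, among them Ptprc, Tyrobp and Laptm5, were above background on no array, and the 4 measured went both ways (Cd68 1.26, Lyz2 -1.74; median 0.69, or 0.22 without control replicate 1), where such cells would need all to fall, so they are an unlikely source of the whole shift. The control arrays lay in 1 row of the slide and the phorone arrays in another, so row and phorone cannot be told apart, whereas the columns held both groups and gave list medians of -1.69 and -2.72, with all 24 genes lower in each.

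The extracellular matrix list was lower, 21 of 24 genes. Here too the test by members still called was undecided, with 12 at the fewest against 18 set beforehand. The median test added afterwards gave -1.30 at the highest, with an upper quartile of at most -0.35. With the same limits, these scalings do not account for the whole of the shift. Another cell line on the phorone arrays stays open. Of 15 body position genes above background on both control arrays, 14 (93.3%) were so on both phorone arrays, and 7 of the 15 were lower. That share passed the 80% first taken as speaking against it, but 94.8% of all genes were kept too, so the bound did not discriminate. The other part of that criterion was met: of body position genes on neither control array, 0 were above background on both phorone arrays. Hoxd8 and Hoxd9 appeared on 1 phorone array each. Hoxd9 did so on 1 probe (-1.81 on phorone replicate 1) but not on another (-6.98). Denser or growth-arrested control cultures cannot be told apart from an effect of phorone, and the labels give no cell density at harvest. Growth arrest genes were lower (median -0.86) and replication genes higher in camera at the preset correlation (adjusted p = 7.4e-05 and 3.5e-04). With an estimated correlation, which could hardly call any list, the values were 0.213 and 0.463. Mitosis genes were not called by camera with all arrays (adjusted p = 0.174). Their median was 0.21, and 0.35 without phorone replicate 1. The lower matrix expression may therefore reflect phorone, a difference in culture state or in cells, or the row of the slide (within the columns the list medians were -1.72 and -1.83).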

How the results depend on the processing

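Spike-in scaling, the joint fit with noncoding probes and the fit without the corner of dark probes were added after the data had been seen. The replicate numbers did not pair the samples (correlation of deviations -0.020), and with the replicate block 3631 genes were higher and 3369 lower, among them 4 and 5 ATF4 targets. A slide block was not run, as there was 1 slide. Over all alternatives, 2046 values of single named genes kept their direction and their side of the threshold, 88 lost and 8 gained the call in the same direction, and 10 changed sign, of which Mt1 was called without control replicate 2.

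Higher calls ranged from 2086 (without phorone replicate 2) to 3961 (without control replicate 1) with 1 array left out, where the lone array of a group is taken to vary like the other group, and numbered 2305 with no filter. Calls of at least 2-fold were 852 higher and 1359 lower with normexp and 753 higher with normexp and quantile normalisation. Spike-in scaling gave 2931 higher and 1046 lower, every call being at least 2-fold. The spike-in level was 12.3 and 13.1 on the control arrays (log2 scale) and 11.9 and 11.7 on the phorone arrays. The 75th percentile was 9.45 and 9.55 on the control arrays and 9.14 and 9.16 on the phorone arrays, so control replicate 2 stood apart. This widened the spread between the control arrays, and Atf3, Trib3, Cdkn1a, Mt1 and Col1a1 all had an SE of 0.47. Counts under this scaling therefore depend largely on the spike-in level of control replicate 2. With an estimated correlation 0 lists were called either way. That estimate leaves camera with 2 residual degrees of freedom, so its lack of calls says little about the shifts either way. Fry called 10 lists higher and 12 lower. Of the lists that camera did not call, fry called glutathione, aryl hydrocarbon receptor, autophagy, repair and p53 genes higher (adjusted p = 0.0067 to 0.0370). Endoplasmic reticulum, apoptosis and adipocyte genes were called lower by fry (adjusted p = 0.0140, 0.0281 and 0.0386). At the preset correlation camera's adjusted p for the called lists ran from 2.8e-11 (matrix) to 0.0475 (osteoblast markers). For the matrix list it was 0.324 with the estimated correlation.

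Among the named genes, and among lists by camera's direction, signs turned for some that were not called and for 0 that were. Among all called genes 246 turned under spike-in scaling, 117 with the mean of a gene's probes and 21 under normexp with the 75th percentile. Without the corner of dark probes 4 turned, with no filter 1 and under the others 0. Under spike-in scaling the list medians were 0.35 (ATF4), 0.55 (glycolysis) and 0.52 (epithelial), and the log2 fold changes 0.22 (Atf3), 0.18 (Trib3), 0.28 (Cdkn1a), 0.34 (Mt1) and 0.21 (Col1a1). Camera's direction for the epithelial list turned with no filter (median 0.14), and fry's differed from it for glycolysis (median 0.039) and macrophage markers (median 0.69). With 1 array left out, medians ranged from -0.26 to 0.029 (ATF4), -0.11 to 0.19 (glycolysis), -0.21 to 0.22 (epithelial) and 0.22 to 0.81 (macrophage), and fold changes from -0.80 to 0.14 (Trib3), -0.49 to 0.016 (Cdkn1a), -1.02 to 0.67 (Mt1) and -0.43 to 0.70 (Mt2). The cause was not tested. Dim genes limit the rest: 235 tested genes were on neither control array well above background and 539 on neither phorone array.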

Other observations

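Lists written after the data had been seen gave a further view of the phorone arrays. Of 21 genes of fibroblast and mesenchymal identity, 14 were lower and 1 higher (median -1.05; called lower by camera, adjusted p = 0.138 with an estimated correlation), among them the growth factor receptors Pdgfra (-2.98) and Pdgfrb (-1.51) and the transcription factors Prrx1 (-1.45) and Twist2 (-1.45), while Cdh11 was higher on its brightest probe (1.27) and lower on its other probes (-5.92 and -4.68). Of 20 genes of growth arrest and confluence, 14 were lower and 1 higher (called lower by camera, adjusted p = 0.213 with an estimated correlation), including Gas1 (-3.64) and Sfrp1 (-2.84), but also the cyclin Ccnd1 (-2.03). Of 26 liver markers on the array, only 8 passed the filter on dim probes, with 2 higher and 2 lower. Afp and Tat rose, by 5.50 and 1.18, and Hp and Igf2 were at least 12.7-fold and 3.09-fold lower. Of 15 body position genes, 1 was higher and 7 lower. Camera called neither of these last lists. Of the 6 probes for Y-linked genes, 0 were above background on any array, and all 4 Xist probes were so on all 4 arrays. The brightest Xist probe stood at 3.74 and 3.51 on the control arrays and at 1.62 and 3.13 on the phorone arrays (-1.25, not called). The other Xist probes gave -1.79, -1.37 and -0.24, of which only -1.37 was called. The genes named here were chosen after their values had been seen.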
